A study of Homo sapiens with 12 samples.

How the data were processed

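Genomic DNA of the human embryonic stem cell line H9 at passage 29 and of embryoid bodies (EB), the aggregates that these cells form when they differentiate in suspension, was examined at CCGG sites. Per the labels' protocols, 3 kinds of library were made from each DNA sample. HpaII cuts a CCGG site only when its cytosines are unmodified, so the HpaII library holds tags of unmodified sites. MspI also cuts sites with 5-methylcytosine (5-mC) or 5-hydroxymethylcytosine (5-hmC), so the MspI library holds tags of all of these states. In the library called BGT here, DNA was first treated with T4 β-glucosyltransferase, which puts a glucose on 5-hmC and so protects the site from MspI, and the tags stand for unmodified and 5-mC sites. Cut ends were tagged with the enzyme MmeI and the short tags were sequenced on an Illumina HiSeq instrument, per the labels' protocols. The labels list 12 libraries in 6 groups of 2, each group being a cell type and a library kind. Per the labels, the MspI samples carry MspI in their titles while their descriptions call them an HpaII library, though one of all 3 cytosine states. The titles and the deposited readme were followed, and every ratio to MspI rests on that reading. The labels do not say whether the 2 replicates of a group came from separate cultures.

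The deposited values are a signal, a normalized tag abundance per site, with 1 value per site for each library kind of a cell type, per the deposited readme and the values. The authors combined the replicates of a group in a way that is not given in the sources used here. The aligner, the normalization and the site filter are likewise not given in the sources used here, and the genome build is hg19, per the submitters' processing notes. The abundances are not whole numbers (0% of them are) and every listed site has a value above 0 in all 3 libraries. The deposited files also hold a p-value from a Poisson test and its false discovery rate (FDR) for HpaII against BGT and for BGT against MspI at each site, per the deposited readme. Recomputing showed that at 100% of sites the deposited p-value equals, within a relative tolerance of 1 part in 10000, the Poisson probability of exactly the second abundance given the first as the mean, both truncated to whole numbers. It is the probability of that single value and not of a tail, and it is set to 0.95 where BGT truncates to 0. As no counts are given, the sequencing depth behind a value is unknown, and no counting interval or floor is printed.

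The comparisons planned before the data were examined were count models with replicates, a test of gene lists, profiles around gene starts and the agreement of replicates. None of these could be used, because each deposited value combines the replicates and because the only gene table at hand is on GRCh38 while the sites are on hg19. The planned fallback was used in their place: consecutive windows of 10 kb named by coordinate, with no test. The 18 planned gene lists were not tested and no gene names are given. Every comparison between H9 and EB below therefore has no replicate check, and no p-value of a difference between the cell types is given.

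Sites on chromosome Y were left out. For each of the other sites listed for both cell types, log2(HpaII/MspI) was taken as the measure of unmodified cytosine and log2(BGT/MspI) as the measure of 5-hmC, which lowers it. Sites with an MspI abundance of at least 10 in both cell types were kept. Windows needed at least 5 kept sites, and their value is the mean over sites. Levels per site were computed as HpaII/MspI for unmodified cytosine, (BGT − HpaII)/MspI for 5-mC and (MspI − BGT)/MspI for 5-hmC, each limited to the range from 0 to 1. The reverse quantity (BGT − MspI)/BGT, which has no meaning in the method, was computed as background for 5-hmC. Because the deposited HpaII, BGT and MspI columns of a cell type have nearly equal medians, HpaII/MspI exceeds 1 at many sites and these levels are relative, not absolute shares. A site-level difference was counted at 0.25 or more. Local density is the number of other listed sites within 1 kb, in 4 classes at its quartiles.

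The site minimum, the windows, their minimum of sites, the difference of 0.25, the density classes and the rule for named windows were fixed before the data were examined. The rule names the 5 windows with the largest value in each direction of each comparison, among windows with at least 5 kept sites. The thresholds for counting windows, 1 on the log2 scale for HpaII/MspI (a 2-fold ratio) and 0.5 for BGT/MspI, were chosen after the data had been seen. So were the bins of 5 Mb with at least 100 sites, the comparison of chromosome X with the autosomes, the comparison of adjacent sites, the deciles of HpaII, the windows with at least 8 sites that all moved the same way, and the other tests of the truncated abundances. The other tests were a two-sided Poisson tail, the point probability with the libraries exchanged, and a two-sided conditional binomial test in which both libraries are treated alike, called the symmetric test here. They take abundances as if they were tag numbers, so they compare 2 pooled values at a site and not the conditions. The FDR threshold was 0.05 with the Benjamini-Hochberg adjustment. That adjustment of the deposited p-values gave the same calls as the deposited FDR except at 223 H9 sites for HpaII against BGT.

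To describe how far windows go beyond unrelated sites, values were shuffled among sites of the same density class 20 times. The spread given for values over the genome is the standard deviation (SD) over the 22 autosomes, which are not replicates. Windows were tested on simulated data with the SD of the real sites: among 45086 windows, the threshold of 1 was passed by 92% of the 100 windows shifted by 1.5 and by 100% of the 100 windows shifted by 2, both on the log2 scale, and by 0.236% of the windows that were not shifted. The simulated sites were independent draws from a normal distribution centred on 0. Shuffled real sites passed more often, in 268 windows upwards and 9.50 downwards on average, so 0.236% is too low for the real changes. The symmetric test was tested on libraries simulated with Poisson noise alone, where it called 1 of 1088207 H9 sites and 0 of 1115052 EB sites. This takes 1 unit of abundance as 1 tag, which the deposited values do not bear out. Alternatives were another site minimum (5 or 20), scaling by library totals, autosomes alone, BGT as the denominator, the ratio of summed abundances, other differences and other density windows, all planned, and those chosen after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.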

Results

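The study used restriction libraries to ask where cytosines are unmodified, carry 5-mC or carry 5-hmC in H9 human embryonic stem cells, an established pluripotent line, and in embryoid bodies (EB) grown from them. The labels list 2 libraries in each of 6 groups, but the deposited values combine them, so there are no replicates and the depth behind a value is unknown. Values were listed for 1094840 CCGG sites in H9 and 1125857 in EB, of which 990878 outside chromosome Y were shared. The summed abundances were 29585584 for HpaII, 19922423 for BGT and 21295489 for MspI in H9. In EB they were 34355818, 21973419 and 22305020. The median abundance per site was 13.7 for HpaII, 13.5 for BGT and 13.5 for MspI in H9, and 17.5, 17.1 and 17.3 in EB. Across the shared sites, which are not replicates, the log2 abundances of HpaII in H9 and EB had a Pearson correlation of 0.90. BGT and MspI correlated at 0.90 in H9 and 0.90 in EB, while HpaII and MspI correlated at 0.20 in H9 and 0.17 in EB. An MspI abundance of at least 10 in both cell types was met at 688767 sites, 69.5% of those shared.

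H9 and EB genomes were compared first over all kept sites. The mean unmodified level was 74.7% in H9 and 79.0% in EB, the mean 5-mC level 25.4% and 22.6%, and the mean 5-hmC level 11.2% and 9.50%. EB was thus higher by 4.27 percentage points for unmodified cytosine (SD over autosomes 0.57), lower for 5-mC (difference −2.77, SD 0.93) and lower for 5-hmC (difference −1.72, SD 0.12). Each of these 3 differences had its direction in 22 of 22 autosomes. The reverse quantity that serves as background for 5-hmC was 8.11% in H9 and 8.16% in EB, so most of the 5-hmC level lay within the scatter between BGT and MspI. With the libraries scaled to their totals the differences for unmodified cytosine and for 5-hmC turned to −0.27 and 0.32 percentage points. With a site minimum of 5 in place of 10 they were 2.44 for unmodified cytosine, −2.01 for 5-mC and −1.004 for 5-hmC, and with 20 they were 9.71, −5.89 and −3.02, so their size depends on the minimum. Scaling to library totals moved the median change of log2(HpaII/MspI) from 0.08 to −0.07, a shift of −0.15, and the median change of log2(BGT/MspI) from 0.03 to −0.05.

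At single sites, the unmodified level was higher in EB by at least 0.25 at 120029 of the 688767 sites (17.4%) and lower by as much at 63765 (9.26%). As background, exchanging MspI for BGT as the denominator within a cell type moved the level by as much in H9 at 3.73% of sites upwards and 2.17% downwards, and in EB at 2.39% and 2.35%. This exchange keeps the HpaII value and the cell type. It leaves out the scatter of HpaII and between samples, so it cannot show how many differing sites exceed noise. Scaled to library totals, 81768 sites were higher and 87777 lower, so the excess of higher sites rested on the scaling as deposited.

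Regions that differ between H9 and EB were sought in windows of 10 kb. Of 45086 windows, 407 had log2(HpaII/MspI) higher in EB by at least 1 and 18 lower by as much. A window on chromosome 11 (118510001 to 118520000) was higher by 1.82 ± 0.47 (SD over its 5 sites), with mean HpaII abundance 7.66 in H9 and 14.9 in EB and mean MspI abundance 36.5 and 20.8. Windows on chromosome 14 (74930001 to 74940000), chromosome 2 (101010001 to 101020000) and chromosome 22 (30730001 to 30740000) were higher by 1.69 ± 1.09, 1.65 ± 0.68 and 1.62 ± 0.93, each at 5 of 5 sites. The window with the highest mean, on chromosome 6 (158360001 to 158370000; 1.84 ± 3.10 over 5 sites), had a mean MspI abundance of 4639 in H9 and 78.8 in EB.

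In the opposite direction, 10 of 11 sites of a window on chromosome 11 (114480001 to 114490000) were lower in EB, with a mean change of −1.43 ± 0.93. Its mean HpaII abundance was 16.2 in H9 and 9.33 in EB, and its mean MspI abundance 14.6 and 21.6. A window on chromosome 9 (118910001 to 118920000) changed by −1.25 ± 0.53 over 5 sites, but its mean HpaII abundance was 164.1 in H9 and 164.2 in EB while MspI went from 18.8 to 44.5. Changes of −1.23 ± 1.36 (7 sites), −1.19 ± 0.69 (5 sites) and −1.16 ± 0.55 (5 sites) were found on chromosome 5 (280001 to 290000), chromosome 5 (156180001 to 156190000) and chromosome 6 (780001 to 790000).

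Among the 407 windows higher in EB, the median change was 0.66 for HpaII and −0.47 for MspI, and 44 had HpaII higher by at least 1. Shuffled sites gave on average 268 such windows (at most 295) and 9.50 lower ones (at most 19). With a site minimum of 5 there were 337 higher and 93 lower windows, and with 20 there were 327 and 0, so the number of lower windows depends on the minimum. In the 15486 windows with at least 8 sites, all sites were higher in EB in 143, against 65.5 in shuffled data (at most 88), and all were lower in 14, against 11.4 (at most 17). With HpaII alone, which had a median change of 0.26 over all sites, 145 windows were higher by at least 1 and 0 lower, against 68.15 (at most 86) and 0.05 in shuffled data. With library totals, 143 windows were higher and 87 lower, and after centring within density classes 200 were higher and 47 lower.

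How far the change between H9 and EB depends on local site density was examined next. Isolated sites, with no other listed site within 1 kb, had a median change of log2(HpaII/MspI) of 0.06 in EB against H9, and sites with 8 to 14 neighbours one of 0.41. Dense sites (the class with 3 to 14 neighbours) exceeded isolated sites by 0.13 (SD over autosomes 0.06), and did so in 22 of 22 autosomes. Each library taken singly rose from H9 to EB in both classes, and rose less at dense sites: by 0.19 against 0.35 at isolated sites for HpaII, 0.12 against 0.39 for BGT and 0.05 against 0.34 for MspI. The mean unmodified level rose from 71.9% at isolated to 78.9% at dense sites in H9, and from 75.8% to 84.5% in EB. The 5-mC level went from 28.6% to 21.2% in H9 and from 27.5% to 15.1% in EB. Across sites, the change of HpaII/MspI correlated with the change of MspI at −0.74 and with that of HpaII at 0.65. Each of these changes is a part of the ratio, so both correlations are partly built in. The changes of HpaII and MspI correlated with each other at 0.02.

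**Figure D1:**
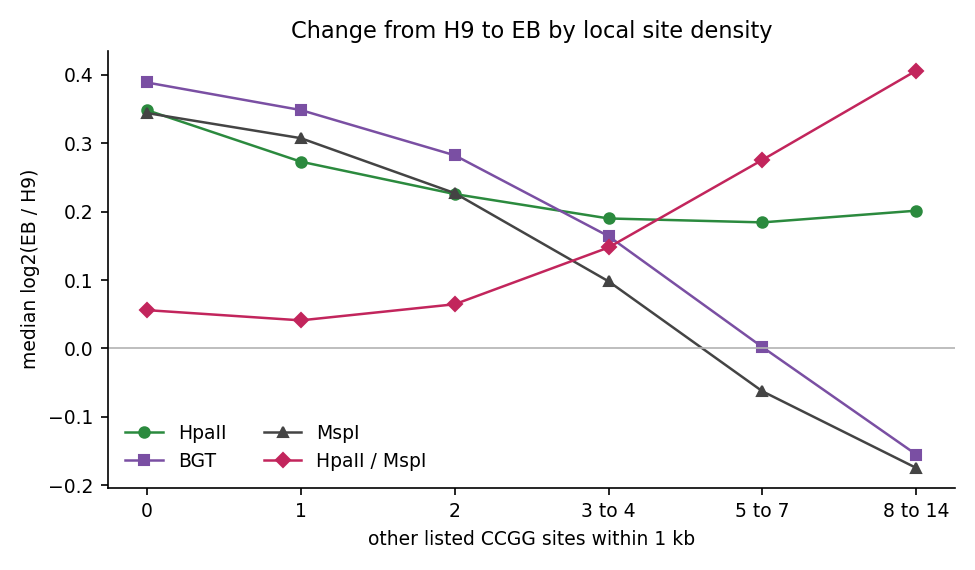
Median log2 ratio of EB to H9 (vertical axis) for the HpaII, BGT and MspI abundances and for HpaII/MspI, by the number of other listed CCGG sites within 1 kb (horizontal axis). MspI goes from 0.34 at isolated sites to −0.17 at sites with 8 to 14 neighbours, while HpaII/MspI goes from 0.06 to 0.41.

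Chromosomes were then compared within each cell type. Chromosome X stood apart: its median log2(HpaII/MspI) was 0.61 in H9 and 0.55 in EB, while the medians of the 22 autosomes lay between −0.35 and −0.06 in H9 and between −0.23 and 0.03 in EB. Chromosome 19 was the highest autosome in both cell types. X exceeded the autosomes by 0.88 in H9 (1.84-fold; SD over autosomes 0.06) and by 0.71 in EB (1.64-fold; SD 0.05). Nearly all of it was in HpaII, where X exceeded the autosomes by 0.87 in H9 and 0.75 in EB. MspI differed by −0.11 and 0.01. At the 90th percentile of HpaII abundance the order was reversed, with X minus autosomes at −0.20 in H9 and −0.15 in EB. The median change from H9 to EB was −0.09 on X, against 0.05 to 0.17 on the autosomes, a difference that does not depend on the scaling of whole libraries. It lay mainly in MspI, which changed by 0.35 on X against 0.13 to 0.30 on the autosomes, while HpaII changed by 0.23 on X, within the autosomal range of 0.19 to 0.30. The mean unmodified level on X, which is limited to 1 at each site, was 89.3% in H9 and 91.5% in EB. It thus rose while the median log2(HpaII/MspI) fell, so the direction of the change on X depends on the measure.

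**Figure D2:**
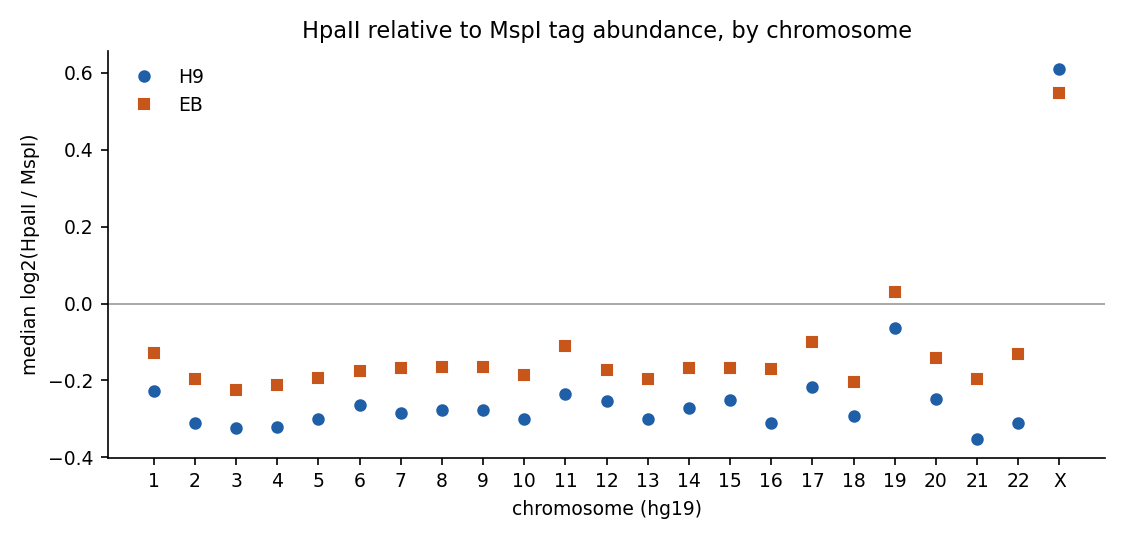
Median log2(HpaII/MspI) per chromosome (vertical axis) over sites with an MspI abundance of at least 10, for H9 (circles) and EB (squares). X, at 0.61 and 0.55, lies above all 22 autosomes, of which chromosome 19 is the highest.

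Along X, 29 of 31 bins of 5 Mb had a median above 0 in H9, against 23 of 561 autosomal bins. The exceptions were the bins from 90 to 95 Mb, at −0.39 in H9 and −0.26 in EB, and from 110 to 115 Mb, at −0.34 and −0.29, both near the median autosomal bin of −0.29 in H9. The autosomal bin with the highest median lay on chromosome 11 from 50 to 55 Mb, at 1.18 in H9 and 0.90 in EB over 106 sites. It was followed by chromosome 13 from 15 to 20 Mb (0.66 in both cell types) and chromosome 6 from 25 to 30 Mb (0.56 and 0.49, over 1460 sites). The lowest was chromosome 1 from 140 to 145 Mb, at −0.75 and −0.86 over 159 sites. Its median log2 abundances in H9 were 5.08 for HpaII and 5.58 for MspI, against 3.91 and 4.14 over autosomal sites. Its low ratio thus went with high MspI and not with low HpaII. These bins were singled out after their values had been seen.

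**Figure D3:**
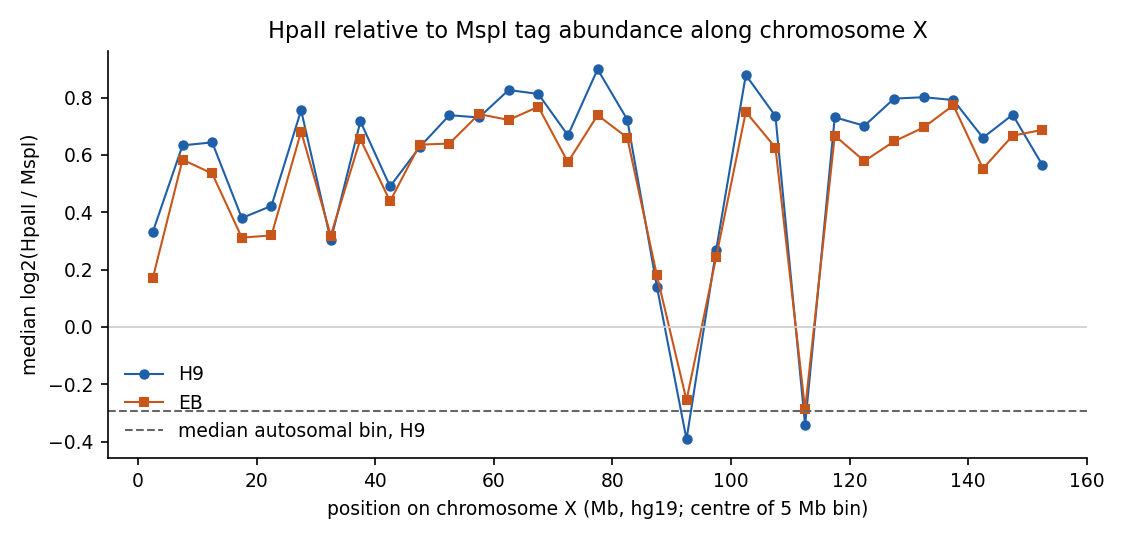
Median log2(HpaII/MspI) (vertical axis) in bins of 5 Mb along chromosome X (horizontal axis, Mb on hg19) in H9 (circles) and EB (squares), with the median autosomal bin of H9 as a dashed line. The bins starting at 90 and 110 Mb lie near the autosomal line and the other 29 lie above 0 in H9.

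Where H9 and EB carry 5-hmC was examined from BGT against MspI, since glucosylated 5-hmC is lost from BGT. In H9, 450 of 45086 windows had log2(BGT/MspI) at or below −0.5 and 33 at or above 0.5. In EB the numbers were 279 and 23. With library totals, 120 windows were low in H9 and 215 in EB, so the order of the cell types depends on the scaling. The lowest H9 window was on chromosome 3 (46700001 to 46710000), at −0.97 ± 0.51 (SD over 5 sites) in H9 and −0.73 in EB. Windows on chromosome 6 (36210001 to 36220000), chromosome 6 (8230001 to 8240000), chromosome 2 (11060001 to 11070000) and chromosome 7 (100770001 to 100780000) followed at −0.86, −0.84, −0.82 and −0.81 in H9, and had −0.22, −0.17, −0.46 and −0.35 in EB. The lowest EB window was on chromosome 17 (21260001 to 21270000), at −1.03 ± 0.59 in EB and −0.70 in H9. Next came X (54510001 to 54520000), chromosome 21 (36210001 to 36220000), chromosome 7 (840001 to 850000) and chromosome 3 (11630001 to 11640000) at −0.93, −0.92, −0.87 and −0.81 in EB, with −0.67, −0.55, −0.78 and −0.37 in H9.

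As background, the highest values of BGT over MspI, to which the method gives no meaning, were 0.71 in H9 (chromosome 2, 157170001 to 157180000) and 0.66 in EB (chromosome 5, 92730001 to 92740000). The other named windows of this kind were at 0.67, 0.63, 0.62 and 0.61 in H9, on chromosomes 5 (from 21480001), 7 (from 139760001), 5 (from 138720001) and 9 (from 118910001). In EB they were at 0.60, 0.59, 0.58 and 0.56, on chromosomes 14 (from 51700001), 11 (from 89950001), 8 (from 71310001) and 5 (from 178130001). Windows low in both cell types numbered 46, against 2.78 for independent lists. In the background direction, BGT over MspI, 2 windows were shared against 0.0168, too few to tell whether sharing was particular to low BGT. These expectations take no account of site number or abundance. Shuffled sites gave 290 low windows in H9 (at most 324) and 154 in EB (at most 176). The minimum on MspI favours low ratios: without it the median log2(BGT/MspI) was −0.003 in H9 and −0.004 in EB. With the minimum set on the geometric mean of BGT and MspI, the low windows numbered 250 in H9 and 203 in EB.

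BGT/MspI was then compared between the cell types. It was higher in EB by at least 0.5 in 458 windows, against 409 in shuffled data (at most 440), and lower in 196, against 189 (at most 211). Most of these windows were thus within what unrelated sites gave. With library totals 178 were higher and 524 lower, so the direction depended on the scaling. With a site minimum of 5 there were 521 higher and 482 lower, and with 20 there were 101 and 36. With the minimum on the mean of BGT and MspI there were 374 and 332, so the excess of higher windows also depended on the minimum. The largest increases were on chromosome 11 (65450001 to 65460000; 0.89 ± 0.46), X (99940001 to 99950000; 0.88 ± 0.45), chromosome 7 (125630001 to 125640000; 0.87 ± 1.65), chromosome 11 (67240001 to 67250000; 0.85 ± 0.64) and chromosome 15 (90270001 to 90280000; 0.83 ± 0.56). The largest decreases were on chromosome 16 (48190001 to 48200000; −0.81 ± 0.68), chromosome 9 (118910001 to 118920000; −0.78 ± 0.75), chromosome 3 (16920001 to 16930000; −0.74 ± 0.59), chromosome 5 (176920001 to 176930000; −0.74 ± 0.67, lower at 7 of 7 sites) and chromosome 2 (131670001 to 131680000; −0.73 ± 0.65). In this order, the windows of decrease began in H9 at 0.34, 0.61, 0.27, 0.44 and 0.23. There BGT was above MspI, to which the method gives no meaning. In EB they were at −0.47, −0.18, −0.47, −0.30 and −0.50. The windows of increase went from −0.70, −0.54, −0.74, −0.31 and −0.80 in H9 to 0.19, 0.34, 0.12, 0.54 and 0.03 in EB, so they ended above 0.

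Site by site, the authors' deposited table compares BGT with HpaII to find 5-mC. At an FDR under 0.05 in the authors' deposited table, BGT was above HpaII at 311561 H9 sites (28.5%) and 353065 EB sites (31.4%), and HpaII was above BGT at 356281 (32.6%) and 388915 (34.6%). HpaII tags stand for only part of the states in BGT, so HpaII above BGT names no cytosine state on an absolute scale. Scaling to library totals shifted the median log2(HpaII/MspI) by −0.47 in H9 and −0.62 in EB. The calls were not recomputed with that scaling. In H9, the sites called with BGT higher had median abundances of 8.97 for HpaII and 20.8 for BGT, and those with HpaII higher had 37.6 and 11.2. Among the shared sites, the calls in the authors' deposited table gave BGT higher in both cell types at 183712 sites and HpaII higher in both at 290499. By the authors' deposited table, 14230 sites went from BGT higher in H9 to HpaII higher in EB, and 4861 the other way.

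The symmetric test called fewer sites and turned the order of the cell types, with BGT above HpaII at 105421 H9 sites (9.63%) and 87757 EB sites (7.80%). EB stayed higher with the two-sided Poisson tail (222069 in H9, 243983 in EB) and with the libraries exchanged (273135 and 319647). Under the symmetric test, 1148 sites went from BGT higher in H9 to HpaII higher in EB and 15 the other way. At the 1148 sites the median BGT abundance was 81.6 in H9 and 21.2 in EB and the median MspI abundance 62.9 and 22.4, with median log2 changes of −1.87 and −1.47. Their median HpaII abundance was 39.5 in H9 and 51.2 in EB, a median log2 change of 0.36. These sites were selected on HpaII and BGT, so the directions of these changes are partly set by the selection.

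For 5-hmC, the authors' deposited table compares MspI with BGT. At an FDR under 0.05 in the authors' deposited table, MspI was above BGT at 35890 H9 sites and 21947 EB sites, and BGT was above MspI at 19852 and 8331. With the libraries exchanged in the same formula, 24116 H9 sites had MspI higher and 27926 BGT higher, and in EB 13821 and 13735. The excess of sites with MspI higher thus turned in H9 and nearly ended in EB. The symmetric test called MspI higher at 2578 H9 sites and 1772 EB sites and BGT higher at 779 and 149.

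By that test, 884 sites had MspI above BGT in both cell types and 5 had BGT above MspI in both. Sites matched for abundance in 1000 bins would share 240 and 1.31 calls if the cell types were independent. The median ratio of MspI to BGT at the 884 sites was 2.32 in H9 and 3.15 in EB. The largest mean ratio, among sites with all 4 abundances below 1000, was at chromosome 13, position 98721300, where MspI and BGT were 400.2 and 109.8 in H9 and 167 and 12.5 in EB. At chromosome 2, position 56850430, they were 276 and 71.3 in H9 and 238 and 21.8 in EB. These positions were chosen after their values had been seen. The 884 sites were most frequent among isolated sites, at 16.5 per 10000, and least among dense ones, at 2.13 per 10000. By HpaII abundance, 511 of them fell in the 9th decile, 58 in the highest and 0 in the lowest 5 deciles. These frequencies were not matched for abundance. The median MspI abundance of the 884 sites was 190 in H9 and 163 in EB, against 13.5 and 17.3 over all listed sites. Over kept sites the mean 5-hmC level was instead lower at isolated than at dense sites, at 10.6% against 11.7% in H9 and 8.63% against 10.4% in EB. The reverse quantity that serves as background was 7.91% at isolated and 8.93% at dense sites in H9, so it rose as well. In EB it was 8.91% and 7.46%, and at isolated EB sites it exceeded the 5-hmC level. Only 0.45% of the 884 sites had another such site within 1 kb, against 0.32% for sites matched for abundance (at most 0.68%).

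Adjacent sites were compared to see over which distances each measure is shared. For log2(HpaII/MspI), sites at most 50 bp apart correlated at 0.61 in H9 and 0.66 in EB, and sites 5000 to 20000 bp apart at 0.10 and 0.07. The change from H9 to EB correlated at 0.08 within 50 bp and 0.12 at 50 to 100 bp. For BGT/MspI the correlation within 50 bp was 0.05 in H9 and 0.07 in EB, and for its change between the cell types 0.003. Across windows within a cell type, the mean levels of 5-mC and 5-hmC had a Spearman correlation of −0.23 in H9 and −0.26 in EB. Both levels contain BGT with opposite signs, and windows are not independent replicates.

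**Figure D4:**
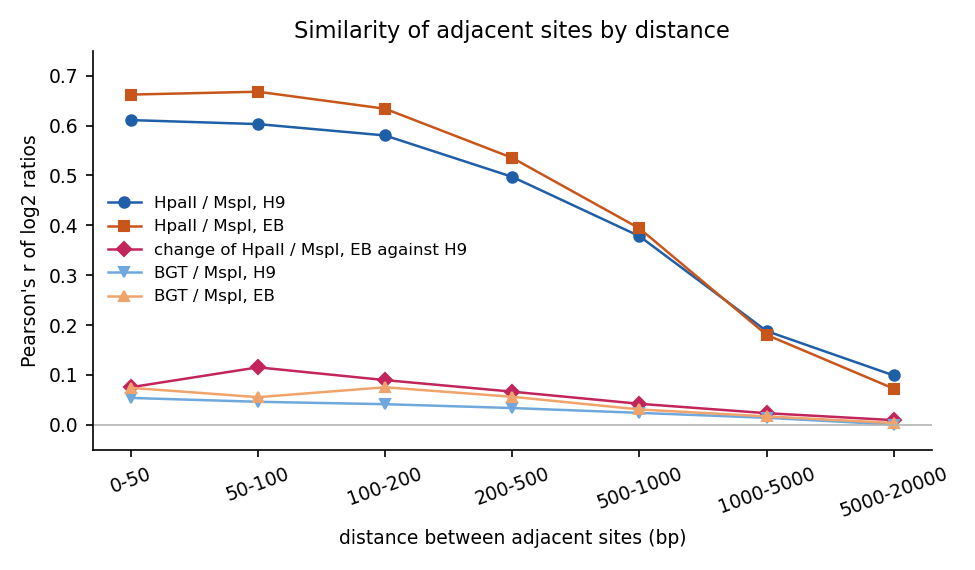
Pearson correlation across pairs of adjacent listed sites (vertical axis) by their distance in bp (horizontal axis) for log2(HpaII/MspI), log2(BGT/MspI) and the change of log2(HpaII/MspI) from H9 to EB. HpaII/MspI starts at 0.61 in H9 and 0.66 in EB and falls with distance beyond 100 bp, while the other measures stay at or below 0.12.

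BGT/MspI was also set against HpaII abundance, over sites with a geometric mean of BGT and MspI of at least 10. In H9 the median log2(BGT/MspI) was −0.05 in the 9th decile of HpaII and 0.06 in the highest. In EB it was −0.09 and 0.04. With HpaII taken from the other cell type, and so from other DNA than the ratio, the values were −0.07 and 0.07 in H9 and −0.08 and 0.04 in EB. Set against the 2nd to 6th deciles per chromosome, the 9th decile was lower by a mean of −0.09 (SD over autosomes 0.04) in H9 and −0.12 (SD 0.04) in EB, in 22 of 22 autosomes in each. On X it was higher, by 0.04 in H9 and 0.03 in EB.

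**Figure D5:**
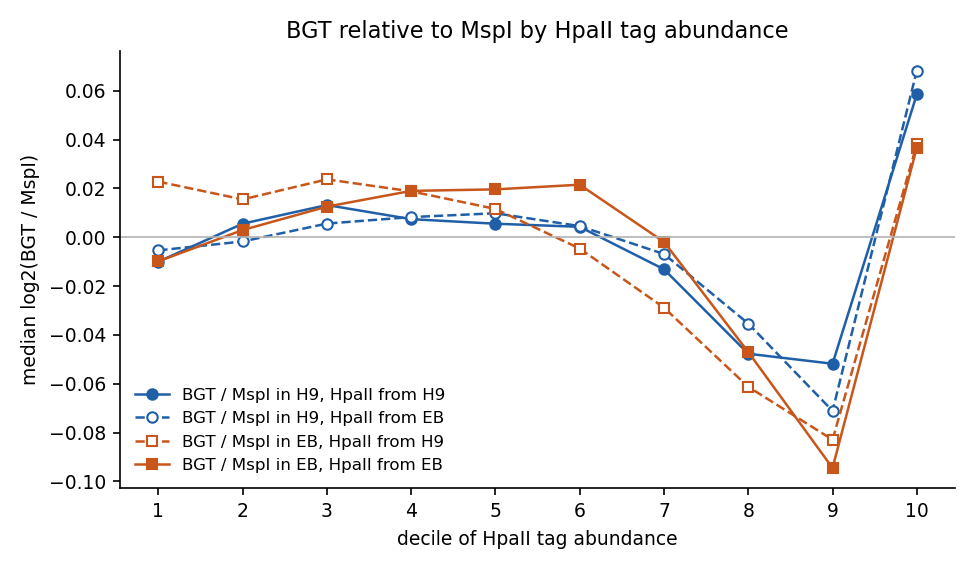
Median log2(BGT/MspI) (vertical axis) by decile of HpaII abundance (horizontal axis) in H9 (circles) and EB (squares), with deciles taken from the same cell type (filled, solid lines) or the other one (open, dashed lines). All 4 lines are lowest in the 9th decile, between −0.09 and −0.05, and lie above 0 in the highest decile.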

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

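All tests named in this part were chosen only after the results were seen. The comparisons of H9 and EB used sites listed for both, so sites listed for one cell type alone are a signal in data that the comparisons did not use. H9 alone listed 103640 sites (9.47% of its sites) and EB alone listed 134580 (11.96%). Their median abundances in H9 were 6.65 for HpaII, 8.62 for BGT and 8.62 for MspI, against 14.7, 14.0 and 14.1 at shared sites. In EB they were 7.53, 12.1 and 11.9, against 19.2, 17.8 and 18.0. The share of such sites was lower on chromosome X than on the autosomes, at 4.49% against 9.69% in H9 and 5.65% against 12.2% in EB. The rule by which sites were listed is not given in the sources used here, so a site missing from a cell type was not necessarily without tags there. No explanation of these sites was tested.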

How the results depend on the processing

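Of 171 values under alternatives for 28 results, 81 stayed within the SD over autosomes (or, for counts, within 1.5 times the count), 85 moved by more without a change of sign and 5 changed sign. Counts cannot change sign, so the 5 sign changes come from the other results, and a turned order of paired counts is not among them. Sites with the unmodified level higher and lower in EB turned to 81768 and 87777 with library totals. H9 calls of MspI above BGT and the reverse turned to 24116 and 27926 with the libraries exchanged. Each of these counts was still within 1.5 times the original. The counts of windows and sites have no error, as the depth behind the values is unknown. With autosomes alone, BGT or the mean of BGT and MspI as denominator, density within 500 bp or 2 kb, windows of 5 kb and X without its 2 lowest bins, all results recomputed stayed in that range. X exceeded the autosomes in H9 and EB under every alternative run for it, and dense exceeded isolated sites under all but HpaII alone. Tests chosen after the data had been seen were HpaII alone, the mean denominator, other window sizes, 10 sites per window, centring, the minimum on the mean of BGT and MspI, X without 2 bins and the 3 other tests of deposited calls. Except where a reason is given, the cause of a move was not tested.

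With 5 MspI tags per site, 93 windows had HpaII/MspI lower in EB, 521 had BGT/MspI higher and 482 lower in EB, and X exceeded the autosomes by 0.78 in EB. The H9 levels were 78.9% unmodified, 22.2% 5-mC and 10.4% 5-hmC, and the EB levels 81.3% unmodified and 20.2% 5-mC. EB minus H9 was 2.44 percentage points for unmodified cytosine and −1.004 for 5-hmC.

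With 20 MspI tags per site, which keeps fewer sites, 0 windows had HpaII/MspI lower in EB, 101 had BGT/MspI higher and 36 lower in EB, and 217 in H9 and 125 in EB had BGT below MspI. Dense minus isolated was 0.20, and X minus autosomes 0.78 in H9 and 0.59 in EB. The levels were 65.2% unmodified, 31.2% 5-mC and 14.2% 5-hmC in H9, and 74.9%, 25.3% and 11.2% in EB. EB minus H9 was 9.71, −5.89 and −3.02 percentage points, and 47810 sites had the unmodified level higher and 8038 lower in EB.

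With library totals, 143 windows had HpaII/MspI higher and 87 lower in EB, 178 had BGT/MspI higher and 524 lower in EB, and 120 had BGT below MspI in H9 against 215 in EB, the reverse of the order as deposited. The levels were 63.3% unmodified, 40.6% 5-mC and 8.56% 5-hmC in H9, and 63.0%, 39.4% and 8.88% in EB. EB minus H9 became −0.27 percentage points for unmodified cytosine and 0.32 for 5-hmC, both of the other sign, and −1.13 for 5-mC. This scaling leaves the differences between densities and between X and autosomes as they are by construction.

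With the ratio of summed abundances, which weights sites by abundance and sets no limits at 0 and 1, the levels were 118% unmodified, −26.2% 5-mC and 7.79% 5-hmC in H9, and 136%, −38.2% and 2.02% in EB. The 5-mC levels changed sign because the HpaII sums exceed the BGT sums. EB minus H9 was 17.8, −12.0 and −5.77 percentage points. With a site difference of 0.1, 206375 sites were higher and 130996 lower in EB, and with 0.5 they were 31087 and 11006.

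With the minimum on the mean of BGT and MspI, 31 windows had HpaII/MspI lower in EB, and 374 had BGT/MspI higher and 332 lower in EB. BGT was below MspI in 250 windows in H9 and 203 in EB. The 5-hmC level was 10.0% in H9 and 9.004% in EB, a difference of −1.04 percentage points. With HpaII alone, 145 windows were higher and 0 lower in EB, and dense minus isolated became −0.16, of the other sign because MspI, which rose less at dense than at isolated sites, is left out. With windows of 20 kb, 206 had HpaII/MspI higher in EB, and 299 in H9 and 168 in EB had BGT below MspI. With 10 sites per window, which leaves fewer windows, 40 were higher and 1 lower in EB for HpaII/MspI, 8 higher and 8 lower for BGT/MspI, and 16 in H9 and 9 in EB had BGT below MspI. Centred within the density class, 200 windows had HpaII/MspI higher and 47 lower in EB.

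In place of the calls in the authors' deposited table, the symmetric test gave MspI above BGT at 2578 sites and BGT above MspI at 779 in H9, and at 1772 and 149 in EB. It gave BGT above HpaII at 105421 and HpaII above BGT at 229337 sites in H9, and at 87757 and 246433 in EB, so the cell type with more sites of BGT above HpaII turned from EB to H9. EB kept more such sites with the two-sided Poisson tail (222069 in H9, 243983 in EB) and with the libraries exchanged (273135 and 319647). The two-sided Poisson tail gave MspI above BGT at 17756 and BGT above MspI at 8346 sites in H9, and at 11888 and 2746 in EB. With the libraries exchanged, EB had MspI above BGT at 13821 sites and BGT above MspI at 13735.

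No paired analysis was possible because the deposited values combine the replicates. For that reason size factors, another count test, the low-count filter, the replicate block, leaving out a replicate and the depth minimum for the agreement of replicates were planned but not run. Without an hg19 annotation, other widths around gene starts, the mean over promoters, the gene list tests and 1 site per feature were not run either.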

Other observations

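The tests in this part were chosen only after the results were seen, though BGT as the denominator was among the alternatives planned before the data were examined.

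The higher HpaII/MspI of chromosome X, by 0.88 in H9 and 0.71 in EB on the log2 scale, was set against 3 technical explanations. The site density of X cannot be the whole cause, because the smallest difference between X and the autosomes within a density class was still 0.72. Fewer MspI tags on X made 10.9% of the summed H9 differences in HpaII and MspI taken singly, and a normalization that depends on MspI abundance left a difference of at least 0.41 in every decile of MspI abundance, so neither could give the pattern alone. A normalization that acts on HpaII by another property of the sites, and a difference in methylation of X stay open and were not tested. The study's groups part the cell types and not the chromosomes, so no biological explanation was tested.

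The larger rise of HpaII/MspI in EB at dense than at isolated sites, by 0.13 on the log2 scale, was tested with another denominator. With BGT, a separate library, the difference was 0.12 (SD over autosomes 0.06) and above 0 in 22 of 22 autosomes, which argues against the MspI library alone as the source. All 3 libraries rose less at dense than at isolated sites. Dense minus isolated was −0.16 for HpaII, −0.29 for MspI and −0.26 for BGT (SD over autosomes 0.04 for each). HpaII taken singly thus went against the pattern, and the larger lag of MspI and BGT gave the ratios their direction. The pattern is therefore not a larger rise of HpaII abundance at dense sites. BGT and MspI libraries are both cut with MspI, and a step or normalization shared by them stays open. A difference between pluripotent and differentiating cells also stays open and was not tested.

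The excess of sites with MspI above BGT over the reverse in the authors' deposited table, 35890 against 19852 in H9 and 21947 against 8331 in EB, was compared with libraries simulated with Poisson noise alone. There the same formula called 52871 against 24705 sites in H9 and 56305 against 29685 in EB, more in each direction than in the authors' deposited table. The simulation takes 1 unit of abundance as 1 tag, and the deposited libraries scattered less than that. It thus shows that the formula can give such an excess from noise, but not how much of the deposited excess it gave. With the libraries exchanged in the formula the excess turned in H9 (24116 against 27926) and nearly ended in EB (13821 against 13735), while the symmetric test kept an excess, 2578 against 779 sites in H9 and 1772 against 149 in EB, so whether the formula is the whole source stays open. For that test the values argued against noise that is independent between the cell types, since 884 sites were called in both and 240 were expected at matched abundance in 1000 bins. With matching in deciles 60.7 were expected, so the expectation depends on how finely abundance is matched. In the reverse direction, to which the method gives no meaning, 5 sites were shared against 1.31. These are too few to tell whether sharing is particular to MspI above BGT. Sites called in opposite directions were fewer than expected in 1000 bins. MspI was above BGT in H9 and below it in EB at 17 sites, against 34.6, and the other way at 0, against 17.5. The 884 sites could come from 5-hmC in both cell types and equally from a site property that lowers BGT tags in each. No biological explanation was tested because the design names no group that lacks 5-hmC.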
